A study of Homo sapiens with 12 samples.

How the data were processed

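Chromatin immunoprecipitation followed by sequencing (ChIP-seq) for trimethylated lysine 27 of histone H3 (H3K27me3), the mark of Polycomb repression, was available as 1 peak list for each of 6 ependymomas. The labels place 3 tumours in the posterior fossa with low global H3K27me3 (PF) and 3 in the supratentorial compartment with high global H3K27me3 (ST). Samples were grouped by the tissue label, and replicate numbers follow the order of the samples and only name tumours. A further 6 input samples have no file used here. Per the labels, tissue was fixed with formaldehyde and sonicated, chromatin was precipitated with an antibody from Cell Signaling Technology, and libraries were sequenced on an Illumina instrument.

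Per the submitters' processing notes, Bowtie 1.0.0 and bedtools were used with the hg19 (GRCh37) build. The peak caller, its thresholds and its use of the input libraries are not given in the sources used here. Each list was made separately for its tumour, has 10 columns and no header, so the meaning of each column was read from its values. Peak widths were whole multiples of 200 bp in every autosomal peak, and all ends lay within the hg19 chromosome lengths. Columns 5 and 6 of the deposited lists were read as 2 probabilities per peak, and the value in column 6 never exceeded that in column 5. Whether they are p-values or probabilities of another kind is not stated in the sources used here. They are called the authors' or caller probabilities below. Column 7 of the deposited lists was read as a signal, the mean number of reads per 200 bp window, because multiplied by the number of windows it gave a whole number (within 1e-06) for every peak. Column 8 of the deposited lists was read as a count, the reads of the highest window, and no peak in any list was under 30. Columns 9 and 10 of the deposited lists hold a fraction each and were read as mappability (the share of the sequence to which reads can be placed uniquely) and GC content. Both were identical across lists for all 382 autosomal intervals that occurred with the same start and end in at least 2 lists. No value in the lists was scaled for depth, and the total number of reads per library is not known from the files used here.

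All values were computed over the 22 autosomes, because peaks on the sex chromosomes would describe a person. From each list the number of peaks, the bases covered and the median width were taken. Lists were compared by the Jaccard index, the bases shared by 2 lists divided by the bases in either. Overlapping or adjoining peaks of all 6 lists were merged into regions, and an overlap of 1 bp made a region present in a tumour. Read counts and probabilities of peaks are the authors' values and are unscaled. They were used to rank, describe and filter peaks. In the closing part they were also compared between lists, without any scaling for depth. Peaks with a mappability of at least 0.9 are called high-mappability peaks, and for a region the width-weighted mean over its peaks was used. That threshold was chosen after the lists had been seen. Region positions are printed as deposited, on hg19. Chromosome bands and their stain came from the hg19 band table of the R package circlize 0.4.16 (R 4.3.3), not from the deposited data. Bands stained as centromeric, variable or stalk were counted together. Genes are named only as general background for a band. The order of the HOX genes came from the GRCh38.p14 gene table, with no coordinate taken from it. Results for 2 loci are not reported here.

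Groups were compared with an exact permutation test of the difference of means, two-sided, over the 20 assignments of 6 tumours. With 3 tumours against 3 the smallest p this test can give is 0.1, so no comparison could pass 0.05. Peak sharing was tested over the 10 splits of the 6 tumours into 3 and 3. The regions named were, before the data were examined, set to be the 5 with the most covered bases among those with a peak in all 3 tumours of one group and in no tumour of the other. Further regions were named after their values had been seen, and the text says which. Intervals of shares are 95% Wilson intervals and cover counting error only. The code that counts regions was tested on simulated lists with planted regions, and 200 of 200 PF-only, 40 of 40 ST-only and 100 of 100 common regions were recovered. Planted peaks lay far apart and were shifted by at most 200 bp, so recovery checks the code and not the counts from the real lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

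Alternatives set before the data were examined were leaving out each tumour, keeping the strongest 50% of each list by highest count, cutting all lists to the 426 peaks of the shortest, joining peaks less than 3000 bp apart, and requiring an overlap of 50% of the shorter peak. Alternatives chosen after seeing the data were limits on mappability, on the band stain, on the authors' probability (at most 0.0001) and on the highest count (at least 60). Promoter, gene and gene-list results had been planned but were not made, since no hg19 gene annotation was used here. No CpG ratio of peaks was computed because no genome sequence was used here, so base composition rests on the deposited GC fraction.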

Results

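H3K27me3 ChIP-seq peak lists of 3 ependymomas of the posterior fossa (PF) were compared with those of 3 ependymomas from above the tentorium (ST). Ependymomas are glial tumours of the ventricular system and spinal canal. Per the labels, the PF tumours had low and the ST tumours high global H3K27me3, and the comparison asks where along the genome the mark formed peaks in each group. The PF lists held 2004, 1438 and 1734 autosomal peaks for replicates 1 to 3, and the ST lists held 426, 605 and 611. Peaks contained 1807775 to 2162975 reads in the PF lists and 278883 to 465723 in the ST lists. These are sums over called peaks and not library depths, which are unknown here. Each tumour is a separate sample in the labels, so the spread given is that between tumours.

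The PF tumours, labelled as low in global H3K27me3, had more and wider H3K27me3 peaks than the ST tumours labelled as high. The number of peaks was 1725 ± 283 (SD, n = 3) in PF and 547 ± 105 (SD, n = 3) in ST, a 3.15-fold difference. Peaks covered 13.2 ± 1.11 Mb (SD, n = 3) of the autosomes in PF and 1.61 ± 0.380 Mb (SD, n = 3) in ST, an 8.20-fold difference. Median peak width was 4133 ± 306 bp (SD, n = 3) in PF against 1267 ± 231 bp (SD, n = 3) in ST. For each of the 3 measures every PF tumour lay above every ST tumour, and the exact permutation test gave p = 0.1 (two-sided, n = 3 per group), the smallest it can give. The fold in number was 1.42 with at least 60 reads in the highest window and 5.66 with a caller probability of at most 0.0001, and in lists of equal length the folds were 4.70 in bases and 7.36 in median width. A missing peak is a site that did not pass the authors' caller in that library and is not a measurement of absent H3K27me3.

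The fold difference was larger in sequence to which reads can be placed uniquely than in low-mappability sequence, where PF also had more. High-mappability peaks numbered 901 ± 201 (SD, n = 3) in PF and 96.7 ± 56.6 (SD, n = 3) in ST, a 9.32-fold difference. They covered 7.42 ± 0.943 Mb (SD, n = 3) in PF and 0.159 ± 0.0652 Mb (SD, n = 3) in ST, a 46.6-fold difference. Their median width was 4733 ± 503 bp (SD, n = 3) in PF and 733 ± 115 bp (SD, n = 3) in ST. High-mappability peaks wider than 10 kb numbered 238, 206 and 251 in the PF lists and 2, 2 and 5 in the ST lists. Each of these measures gave p = 0.1 in the exact permutation test (two-sided, n = 3 per group). The ST lists kept peaks with column 6 probabilities of up to 0.405 and the PF lists up to 0.00434; at a caller probability of at most 0.0001 the high-mappability folds were 48.6 in number and 133 in bases. In low-mappability sequence the number of peaks differed 1.83-fold, with 825 ± 90.9 (SD, n = 3) in PF and 451 ± 67 (SD, n = 3) in ST. Bases covered there differed 4.00-fold, with 5.82 ± 0.455 Mb (SD, n = 3) in PF and 1.45 ± 0.316 Mb (SD, n = 3) in ST.

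**Figure D1:**
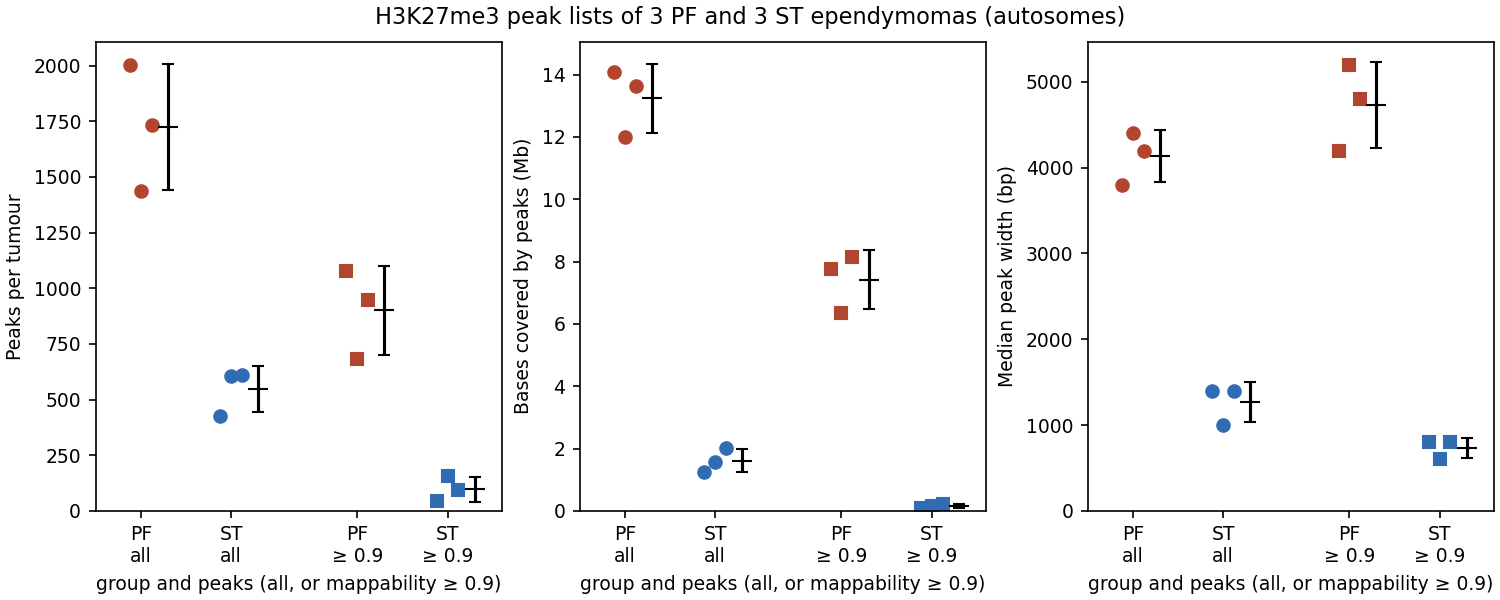
Number of autosomal H3K27me3 peaks, bases covered in Mb and median width in bp for each PF (red) and ST (blue) tumour, over all peaks (circles) and peaks with a mappability of at least 0.9 (squares); bars are mean ± SD of 3 tumours. Every PF tumour lies above every ST tumour, and covered bases at high mappability are 7.42 Mb on average in PF and 0.159 Mb in ST.

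Most peaks of the ST tumours lay in low-mappability sequence, and a larger share than in PF lay in bands stained as centromeric, variable or stalk. High-mappability peaks made up 9.86% (95% Wilson interval 7.38 to 13.1), 25.6% (22.3 to 29.2) and 15.2% (12.6 to 18.3) of the ST lists for replicates 1 to 3. In the PF lists they made up 53.7% (51.5 to 55.9), 47.4% (44.8 to 49.9) and 54.5% (52.1 to 56.8). Centromeric, variable and stalk bands held 35.1 ± 9.03% (SD, n = 3) of ST peaks and 10.6 ± 2.18% (SD, n = 3) of PF peaks, with exact permutation p = 0.1. The strongest peaks by read count were of low mappability in both groups: of the 50 peaks with the highest counts, 98% in each PF list and 98% to 100% in the ST lists had a mappability under 0.9. Median GC content of peaks was 0.476 ± 0.00810 (SD, n = 3) in PF and 0.394 ± 0.0199 (SD, n = 3) in ST, with exact permutation p = 0.1. Among high-mappability peaks it was 0.530 ± 0.00932 (SD, n = 3) in PF and 0.548 ± 0.134 (SD, n = 3) in ST, with exact permutation p = 1. The higher ST mean there rested on ST replicate 2, at 0.695, while ST replicates 1 and 3 were at 0.433 and 0.515, below every PF tumour; without replicate 2 GC content was 0.0559 higher in PF.

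**Figure D2:**
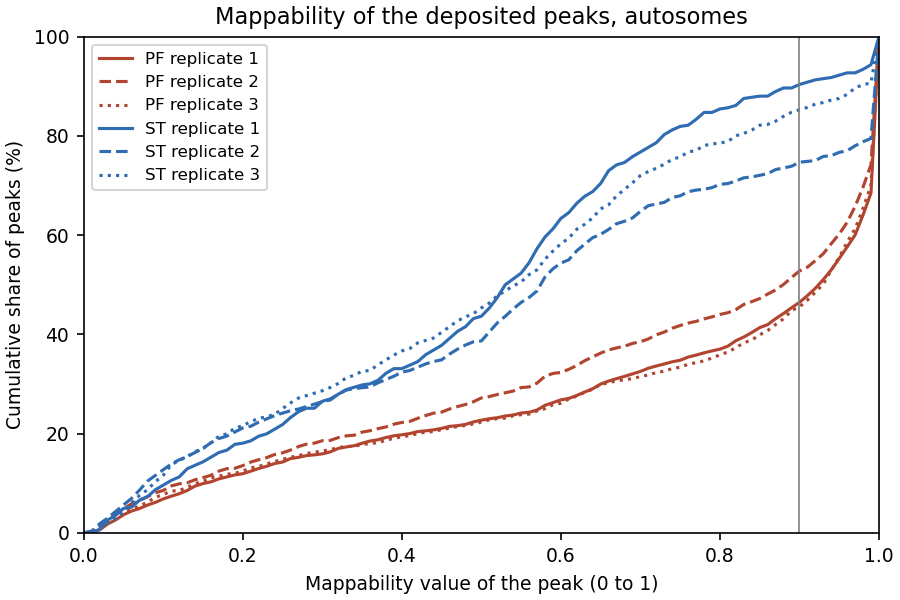
Cumulative share of autosomal peaks (%) against the mappability value of the peak (0 to 1) for each PF (red) and ST (blue) tumour; the grey line marks 0.9. The ST curves rise early, with median mappability of 0.530, 0.576 and 0.548, and the PF curves late, with medians of 0.925, 0.879 and 0.930.

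PF tumours shared a common set of domains, and ST tumours shared their repeat peaks but few others. The Jaccard index was 0.558 ± 0.0273 (SD, 3 pairs) within PF, 0.450 ± 0.0215 (SD, 3 pairs) within ST and 0.0999 ± 0.0222 (SD, 9 pairs) between the groups. Among high-mappability peaks it was 0.538 ± 0.0360 (SD, 3 pairs) within PF and only 0.0842 ± 0.0269 (SD, 3 pairs) within ST, with 0.00891 ± 0.00357 (SD, 9 pairs) between the groups. Among low-mappability peaks it was 0.515 ± 0.0266 (SD, 3 pairs) within PF, 0.494 ± 0.0233 (SD, 3 pairs) within ST and 0.200 ± 0.0353 (SD, 9 pairs) between them. Sharing within minus between groups was 0.404 over all peaks, and 1 of the 10 splits, the real one, gave a value as large (exact p = 0.1, the smallest possible). The index depends on how much of the genome each list covers.

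**Figure D3:**
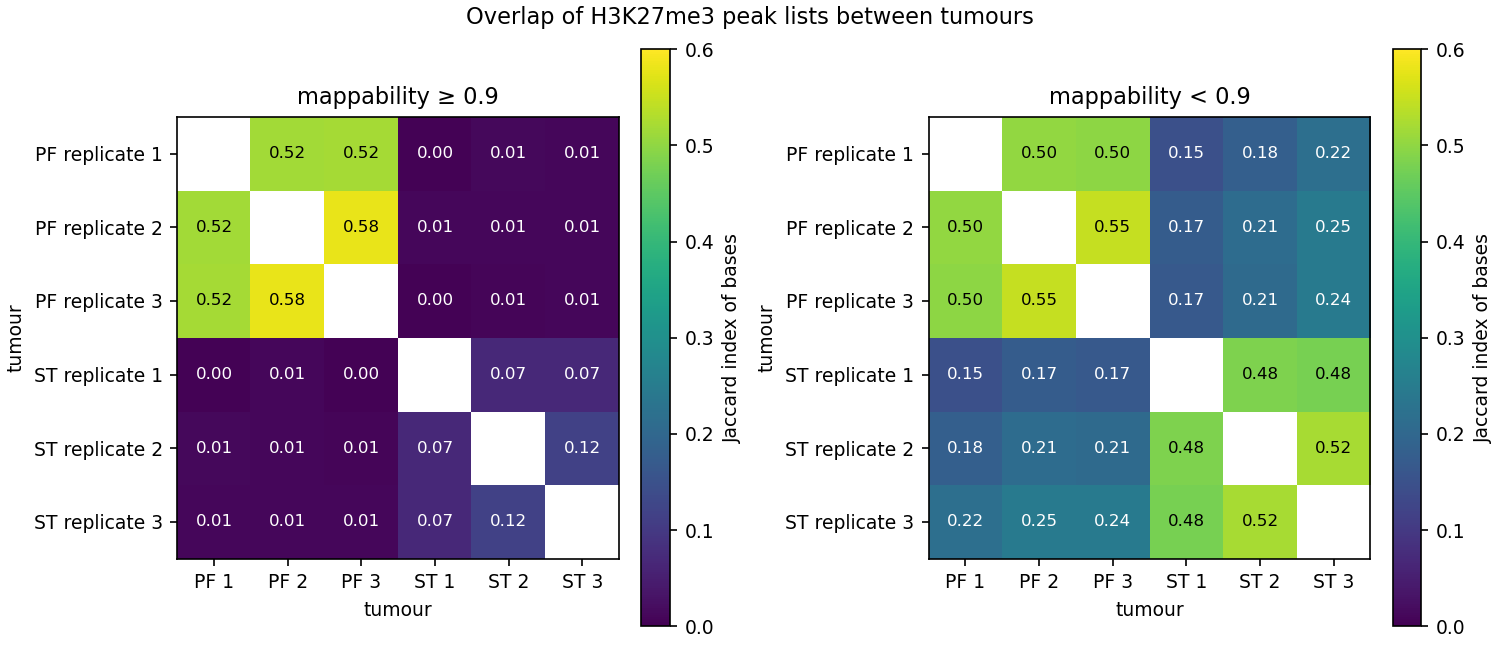
Jaccard index of bases for each pair of the 6 tumours, for peaks with a mappability of at least 0.9 (left) and under 0.9 (right); colour and printed value give the index, and the diagonal is left blank. High-mappability sharing is 0.516 to 0.580 within PF and 0.0685 to 0.115 within ST, while low-mappability sharing is alike within both groups.

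Where ST tumours did have a high-mappability peak, it was usually at a site that was also marked in PF tumours. Of these ST peaks, 88.1% (95% Wilson interval 75 to 94.8), 78.7% (71.6 to 84.4) and 86.0% (77.5 to 91.6) overlapped a peak of at least 1 PF tumour in replicates 1 to 3. Among low-mappability ST peaks the share was as high, at 87.8%, 89.1% and 85.1%, so it was not particular to high-mappability sequence. The union of the PF lists covered 0.678% of the autosomes, which is no expected share, since peaks are not spread evenly over the sequence. In the other direction, 10.9% (9.15 to 12.9), 14.8% (12.4 to 17.7) and 11.2% (9.36 to 13.4) of the high-mappability PF peaks overlapped an ST peak. High-mappability regions with a peak in ST and none in PF numbered 46, and 0 of them occurred in more than 1 ST tumour.

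Recurrent group-specific domains belonged almost entirely to PF. Of 2886 merged regions, 512 had a peak in all 3 PF tumours and in no ST tumour, and 22 had a peak in all 3 ST tumours and in no PF tumour. Among 1513 high-mappability regions these counts were 378 and 0. The 378 regions lay in 230 bands, had a median width of 9800 bp and covered 5.12 Mb together. A further 134 regions had a peak in all 6 tumours, and 5 of these were of high mappability. With lists cut to equal length the counts were 195 PF-only and 41 ST-only regions.

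The 5 PF-only domains with the most covered bases were each covered over 43.5 to 48.1 kb on average in PF and had no peak in any ST list. The rule fixed beforehand gave a domain in 8p23.1 (hg19 chromosome 8, 11531200 to 11582399), a band that holds GATA4, a transcription factor of heart and endoderm. Peaks covered 48.1 ± 0.924 kb (SD, n = 3) of it in PF. In 6p24.3 (chromosome 6, 10380000 to 10430399), the band of the neural crest factor TFAP2A, 48 ± 2.23 kb (SD, n = 3) was covered. A domain in 4q34.1 (chromosome 4, 174420200 to 174468799), the band of the heart and limb factor HAND2, was covered over 47.3 ± 1.22 kb (SD, n = 3). A domain in 17q21.32 (chromosome 17, 46783000 to 46833399), the band of the HOXB cluster of axial patterning genes, was covered over 46.1 ± 4.10 kb (SD, n = 3). In 1q31.3 (chromosome 1, 197855200 to 197907199), the band of the LIM homeobox gene LHX9, 43.5 ± 10.1 kb (SD, n = 3) was covered. The rule selects for this separation, so the domains were not tested singly. Genes are background for their band: overlap of a domain with a gene and enrichment of gene classes were not tested, since no hg19 gene annotation was used.

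A further 8 PF-only domains, picked after their values had been seen and so no sample of all 512, were covered over 28 to 39.7 kb on average in PF. Bands that hold T-box genes were 12q24.21 (TBX3 and TBX5), where a domain at chromosome 12, 115100800 to 115141999, was covered over 39.7 ± 0.902 kb (SD, n = 3), and 1p12 (TBX15; chromosome 1, 119514400 to 119552399), covered over 35.5 ± 1.5 kb (SD, n = 3). Bands that hold DLX genes were 7q21.3 (DLX5 and DLX6), covered at chromosome 7, 96616600 to 96656999, over 38.6 ± 2.31 kb (SD, n = 3), and 2q31.1 (DLX1 and DLX2, forebrain interneuron factors), covered over 29.7 ± 1.94 kb (SD, n = 3) at chromosome 2, 172943600 to 172975399. Domains in 10p14 (chromosome 10, 8074600 to 8112799), the band of GATA3, and 20p11.21 (chromosome 20, 22538800 to 22571799), the band of the floor plate and endoderm factor FOXA2, were covered over 34.1 ± 3.00 kb (SD, n = 3) and 29.8 ± 2.84 kb (SD, n = 3). A domain in 7q36.3 (chromosome 7, 156788400 to 156818799), the band of the motor neuron factor MNX1, was covered over 28 ± 2.51 kb (SD, n = 3). In 9p21.3 (chromosome 9, 21961600 to 21994399), the band of the cell cycle inhibitors CDKN2A and CDKN2B, peaks covered 30.3 ± 2.01 kb (SD, n = 3), at a mappability of 0.897. The 8 domains had no peak in any ST list, and neither copy number nor the input libraries were examined at them.

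High-mappability regions of 51.2 to 116.8 kb lay in the bands of the HOXB, HOXC and HOXD clusters, also named after the values had been seen. In 12q13.13, the HOXC band, a region at chromosome 12, 54312800 to 54429599, was covered over 110.4 ± 4.58 kb (SD, n = 3). In the HOXB band a region at chromosome 17, 46614400 to 46727799, was covered over 51.6 kb, 113.4 kb and 112.4 kb in PF replicates 1 to 3. In 2q31.1, which also holds the HOXD cluster, adjacent regions lay at chromosome 2, 176930000 to 177006399 and 177007600 to 177058799. The first was covered over 75.2 ± 1.06 kb (SD, n = 3), and the other over 9.2 kb, 48 kb and 51 kb. ST replicate 2 alone among ST tumours had peaks in these 4 regions, and they covered 0.4 to 2.4 kb per region. The highest counts of these ST peaks were 33 to 47, and the lowest such count in any list was 30. The authors' lower probability ranged from 0.000692 to 0.320.

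**Figure D4:**
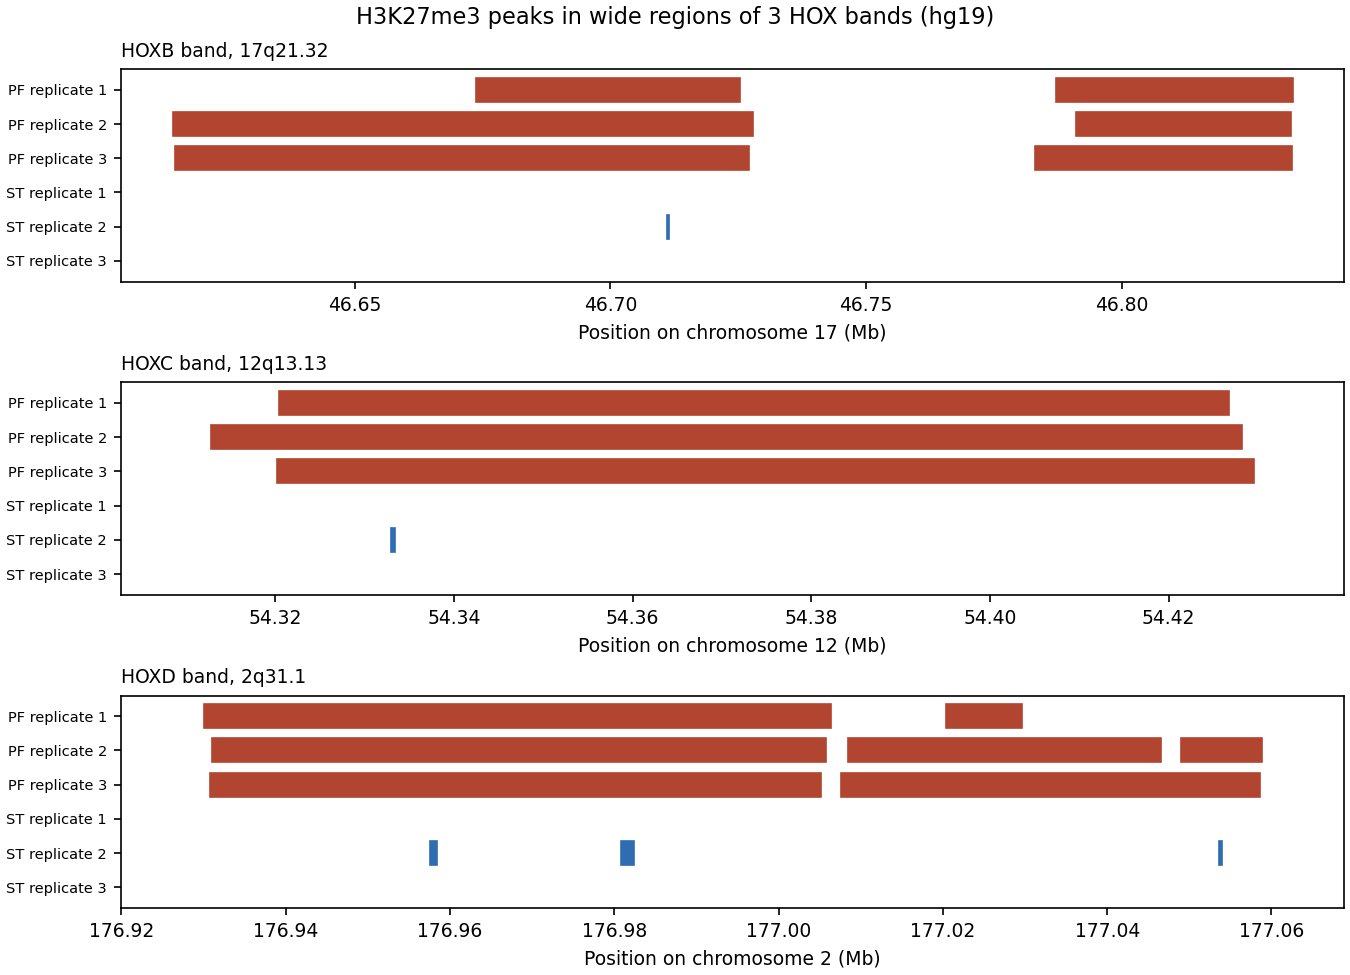
Deposited H3K27me3 peaks (bars, to scale) of each PF (red) and ST (blue) tumour in the regions of at least 50 kb in the bands of the HOXB, HOXC and HOXD clusters; the horizontal axis is the hg19 position in Mb. PF tumours have broad domains, of which PF replicate 1 lacks a part in the HOXB and HOXD bands, and ST replicate 2 has short peaks of up to 1.6 kb.

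Regions found in ST tumours only were of low mappability. All 22 had a mappability under 0.9, with a median of 0.580, and 15 lay in centromeric, variable or stalk bands. The 5 regions given by the fixed rule lay in 7p11.2 (2 regions), 20p11.1, 17q11.1 and 2q21.2. Those in 7p11.2, at chromosome 7, 57974600 to 58001199 and 57956400 to 57972399, were covered over 21.8 ± 5.19 kb and 12.1 ± 3.19 kb (SD, n = 3) in ST. The regions in 20p11.1 (chromosome 20, 26258800 to 26269399), 17q11.1 (chromosome 17, 25296400 to 25307199) and 2q21.2 (chromosome 2, 133013600 to 133029599) were covered over 9.60 ± 0.872 kb, 9.13 ± 1.47 kb and 7.73 ± 7.0 kb (SD, n = 3). Of the 22 regions, 16 had a PF peak within 20 kb. Reads from repeated sequence can be placed at the wrong copy, so positions in these bands are uncertain.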

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

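The alternatives on mappability, band stain, caller probability and highest count were chosen after seeing the data; the others were set before. Direction was kept in all 13 alternatives for the number of peaks (1.42- to 9.32-fold, lowest with at least 60 reads in the highest window; the strongest 50% of each list keeps this ratio by construction) and for the bases covered (4.00- to 46.6-fold), and in all 14 for the median width (2.06- to 7.36-fold). Sharing within minus between groups stayed above 0 in all 15 (0.302 to 0.450), which the lower coverage in ST favours. High-mappability peaks kept their direction in 9 of 9 alternatives (7.26- to 48.6-fold in number, 25.5- to 133-fold in bases). These left out single tumours, set the mappability limit at 0.8 or 0.95, or added the limit on caller probability. The highest folds came with the probability limit, and probabilities at a given highest count were weaker in ST. Limits on highest count, list length, strongest 50%, joining and band stain were not run for high-mappability peaks, so stability under them was not tested. No test could pass 0.05 under any alternative, so p-values say nothing about stability.

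The count of PF-only regions, 512, was 195 with lists of equal length, 127 with mappability under 0.9 and 199 with at least 60 reads, each from fewer peaks. The count of ST-only regions, 22, was 41 with lists of equal length, 1 with mappability of at least 0.9, 7 without centromeric, variable or stalk bands and 14 with a probability of at most 0.0001. Leaving out single tumours gave 527 to 720 PF-only and 22 to 30 ST-only regions. This relaxes the rule, so apart from changes in merging these counts could only stay or rise. The GC difference, 0.0828 higher in PF, was -0.0179 among high-mappability peaks. That sign change came from ST replicate 2: leaving out single tumours gave -0.0754 to 0.0559, and the value without ST replicate 2, 0.0559, was the only one above 0. Promoter, gene and gene-list alternatives were not run, because no hg19 annotation was used. Library depth is unknown, and no list held a peak with a highest count under 30, which limits what absence of a peak can show. Highest counts of 30 to 39 occurred in 11, 91 and 55 ST peaks for replicates 1 to 3. In PF they occurred in 1087, 642 and 859 peaks. The median highest count averaged 62.7 in ST and 40 in PF, so most ST peaks, which were mainly of low mappability, had far more than 30 reads. High-mappability ST peaks lay nearer to that floor: 4 of 42, 85 of 155 and 37 of 93 had highest counts of 30 to 39 in replicates 1 to 3. In PF these were 606 of 1076, 279 of 681 and 443 of 945 high-mappability peaks.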

Other observations

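Apart from the test of depth in ST replicate 2, the bounds of all tests in this part were set after the results had been seen. Within PF, replicate 1 had under 0.6 of the mean coverage of the other tumours in 2 of the 5 wide HOX-band regions reported here. Its peak in the HOXB band began at 46673800, against 46614400 and 46614800 in replicates 2 and 3. In the HOXD band it covered 9.2 kb of the region at the high-coordinate end. In the GRCh38.p14 gene table HOXB1 is the first gene of its cluster in rising coordinate and HOXD1 is the last of its cluster, so in both regions the part with fewer peaks was at the end of the low-numbered paralogs. Those genes are known for expression in the embryonic hindbrain, and the high-numbered ones for expression in the trunk and tail. The region in the HOXC band, whose cluster has no paralogs numbered below HOXC4, was covered over 106.4 kb in the same tumour. Overlap of peaks with single HOX genes was not tested.

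Shorter calls throughout the list of PF replicate 1 do not account for this pattern. Its covered bases divided by the mean of the other PF lists were 0.457 and 0.186 in the partial HOXB and HOXD regions and 0.947 to 1.02 in the other 3 HOX-band regions. Over the 38 other high-mappability regions of at least 30 kb that had a peak in all 3 PF tumours, the median was 0.961, and 1 of them was as low as 0.457. Partial coverage was not particular to this tumour or to HOX bands, since ratios under 0.6 occurred in 2 of the 38 for replicate 1 and in 2 for replicate 2. No biological explanation was tested.

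The larger number of H3K27me3 peaks in tumours labelled as low in the mark is the pattern a reader would most want to follow up. Repeats alone do not account for it, because the PF excess was 9.32-fold at a mappability of at least 0.9. If the probability depends on background reads alone, greater depth of the PF libraries would leave fewer background reads in ST windows. ST probabilities at a given count would then be lower. The ST median probability was the lower in 0 of 36 comparisons of an ST with a PF list (9 pairs of lists, each in 4 classes of highest count). The caller is not known, and its probability may depend on more than background reads, so these comparisons cannot exclude greater depth of the PF libraries. Under the same assumption about the probability, a higher read background in the ST libraries would go with weaker ST probabilities at a given count. At highest counts of 40 to 49 the lowest ST median probability was 0.0529, against at most 3.64e-08 in PF. It stays open whether there was such a background. It also stays open whether it may be diffuse H3K27me3 over the ST genome, as their labels would allow, weaker enrichment in the precipitation, or deeper ST libraries. Reads at identical low-mappability intervals had median ST over PF ratios of 1.12 to 1.58 in the 9 pairs of lists (17 to 49 intervals per pair). An interval entered only if called in both lists. Called ST peaks had higher median highest counts (62 to 64, against 38 to 42 in PF), so these ratios cannot show which libraries were deeper.

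The split of 3 PF against 3 ST tumours gave 534 regions found in one group only, and the highest of the other splits gave 34. For high-mappability regions the real split gave 378 and the highest other 3. In both cases 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.

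ST replicate 2 alone among ST tumours had small peaks in the HOX bands, with the authors' probabilities of 0.000692 to 0.320 against a median of 0.000749 for its whole list. It also held 155 of the high-mappability ST peaks, against 42 and 93 in replicates 1 and 3. Of the 46 high-mappability ST regions without a PF peak it held 29, so its excess was not particular to PF-marked sites. The 155 peaks had a median GC content of 0.695, against 0.433 and 0.515 in ST replicates 1 and 3 and 0.521 to 0.539 in PF. Their median width was 600 bp, and 85 of them had highest counts of 30 to 39. Whether base composition accounts for the small HOX-band peaks was not tested. Its high-mappability peaks covered 0.163 Mb, against 6.35 to 8.15 Mb in the PF tumours, so its coverage was unlike that of the PF lists. Weak enrichment could also lower coverage, so coverage alone cannot exclude that ST replicate 2 is a PF tumour labelled as ST. Greater depth of this library than of the other ST libraries cannot be told apart from other sources, as its reads at identical low-mappability intervals had a median ratio of 1.16 to ST replicate 1 and of 1 to ST replicate 3. No biological explanation was tested.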
